A study of Mus musculus with 10 samples.

How the data were processed

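Messenger RNA levels were measured by sequencing in 10 subcutaneous B16F10 tumours, 5 injected with control mRNA and 5 with a cytokine mRNA mixture. Per the labels' protocols, RNA was extracted with a DNase step, polyA RNA was used, and stranded libraries were prepared with NuGEN methods. The authors deposited 1 table of TPM, a measure of transcript share corrected for transcript length, with a column per tumour and a row per gene symbol, scaled to the same total in each column. Per the submitters' processing notes the aligner was STAR, with no version given, and the genome build was GRCh38. GRCh38 is a human build, while the samples are mouse and the table holds mouse symbols, so the build is left open and no coordinates are given. The gene annotation, the counting program, any filter and the way TPM was computed are not given in the sources used here.

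TPM keeps no sequencing depth. The depth of each library is therefore unknown, and no counting interval or detection limit can be given. A gene listed at 0 may be absent or below what the library could show. Because TPM are shares of a library, a rise of abundant genes lowers the values of all others. A few abundant groups, such as mitochondrial genes, can move every other value.

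The table holds 22329 genes, of which 4824 were at 0 in all 10 libraries. Of the symbols, 21968 matched GENCODE mouse release 21. List members whose symbol had no row were searched through their older names. Cd244a and Gsdme were found as Cd244 and Dfna5, and Mc1r, Acta1, Ahsp, Cox4i1 and Xist are not analysed here.

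Each library was assigned to its group by its title, which names the injected mRNA, and libraries are numbered as in the titles, 1 to 5 for control and 6 to 10 for cytokine mRNA. No number is shared between the groups, so nothing pairs the tumours. The labels give no batch or date. The design states 5 tumours per group, so each library is taken as a separate tumour.

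Genes with a TPM of at least 1 in at least 5 libraries were tested, which left 12497. Values were transformed to log2(TPM + 1), with a pseudocount of 1, and compared with limma version 3.58.1 in R version 4.3.3 (lmFit, then eBayes with a trend), with 2-sided tests. Benjamini-Hochberg adjustment ran over all genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(TPM + 1) scale and understate the change of genes with low values. The limma step was tried on simulated data with 12497 genes, 200 of them changed, and 1 spread per gene pooled over the real groups. It recovered 14% of genes changed 2-fold and 53% of genes changed 4-fold. All of its calls of changed genes had the right sign, 4 calls were false (5.63% of calls), and none of 20 unchanged lists was called. Both simulated groups had the same spread, unlike the real ones, whose T cell list means had SDs of 0.52 and 1.58. The recovered and false shares may therefore differ in the real data. Each simulated gene varied independently of the others. Genes of the real lists did not, with an estimated correlation of 0.706 in the T cell list. The simulation therefore does not show how often an unchanged list of correlated genes would be called.

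Before the data were examined, 36 gene lists were fixed: cytokine and interferon responses, cell types that a subcutaneous tumour could hold, tumour states, tissue handling, and checks. The 31 lists of the first 4 kinds with at least 3 tested genes were compared with other genes by limma's camera with a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. They were also tested by fry, and by an exact 2-sided permutation test of the mean log2(TPM + 1) per tumour over the list. The smallest p the exact test can give with 5 against 5 tumours is 0.00794. Each set of list tests was adjusted by Benjamini-Hochberg over the lists. Counts "adjusted over the list alone" used only the p-values of the list's genes.

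The genes named were also set by rule before the data were examined. They are the 10 called genes with the largest rise and the 10 with the largest fall whose 5 values in 1 group all lie above the 5 of the other, leaving out predicted genes, pseudogenes and receptor segments. To these were added the genes of the injected cytokines, up to 4 called members of each list with the largest change (or the 2 most abundant where none was called), and the sex-linked and reference genes. Some genes that the rule names are not reported here. Genes named outside this rule were chosen after their values were seen, and the text says so.

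Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter on low values, a filter at a TPM of 5, a median-ratio scaling, a rescaling without the 50 most abundant genes, quantile normalization, no trend in the variance prior, library quality weights, an exact rank test, a fold minimum of 2, an adjusted p under 0.01, the other list tests, list medians in place of means, and each library left out in turn. After seeing the data, 2 were added: leaving out libraries 6 and 7 together, and rescaling without mitochondrial and receptor segment genes.

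Library checks were the share of TPM on 13 mitochondrial genes, the share on 477 immunoglobulin and T cell receptor segments, how many of 1483 chemosensory receptor genes (olfactory and vomeronasal) were above 0, and the scatter of 74 ribosomal protein genes around their control means. Similar pseudogenes were counted with blastn version 2.17.0, comparing gene transcripts with 13607 GENCODE pseudogene transcripts at an identity of at least 90% over at least 100 bases. Figures were drawn with matplotlib version 3.10.9.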

Results

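The data are gene expression profiles of 10 tumours grown from B16F10, a mouse melanoma cell line under the skin of C57BL/6 mice. The tumours were injected once, with 80 µg mRNA in total. In 5 control tumours it encoded luciferase, and in the other 5 it was a mixture of 20 µg each of 4 mRNAs encoding mouse single-chain IL-12, IL-15sushi (IL-15 with part of its receptor), GM-CSF and interferon alpha. Tumours were collected 7 days later. Values are TPM, with 11513 to 12984 genes at a TPM of at least 1 per library; the depth is unknown. The design implies 1 comparison: which genes differed between cytokine mRNA and control mRNA tumours at that time.

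Genes of interferon responses, antigen presentation and immune cells were higher in the cytokine mRNA tumours, and genes of cell division were lower. Ly6c2, a monocyte surface protein gene, rose from 10.8 ± 9.33 to 2167 ± 3176 TPM (SD, n = 5 per group). Cd3e, part of the T cell receptor complex, rose from 4.27 ± 2.70 to 329 ± 421 TPM, and Nos2, the inducible nitric oxide synthase, from 1.36 ± 0.925 to 78.6 ± 39.5 TPM. Cdk1, the kinase that drives entry into mitosis, fell from 242 ± 44.2 to 74.7 ± 68.0 TPM. Without library 7 the cytokine mRNA mean was 786 TPM for Ly6c2 and 149 TPM for Cd3e, and without library 10 it was 45.2 TPM for Cdk1. Of 12497 genes tested with limma, 1304 changed at an adjusted p under 0.05, with 926 higher (71.0% of those changed) and 378 lower, and 1196 of them changed at least 2-fold. The groups did not overlap in 1153 genes (9.23% of those tested, against 0.794% by chance).

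The count of changed genes rested on single libraries: it was 577, 680, 554 and 548 without control libraries 2, 3, 4 and 5, and 367, 860, 492, 676 and 3238 without cytokine libraries 6, 7, 8, 9 and 10. Without control library 1 the count of lower genes was 142. The count of changed genes was 20 without libraries 6 and 7 together, all of them among the 1304, and an exact rank test called 0 genes (2914 at an unadjusted p under 0.05). The share of changed genes that were higher was 60.0% after rescaling without the 50 most abundant genes and 55.2% after rescaling without mitochondrial and receptor segment genes. It was 57.5% with library quality weights, and with single libraries left out it ranged from 50.8% without library 10 to 87.5% without library 6. The median change of all tested genes was -0.18 on the log2 scale, and it was -0.03 after median-ratio scaling, -0.28 without the 50 most abundant genes and -0.32 without mitochondrial and receptor segment genes.

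**Figure D1:**
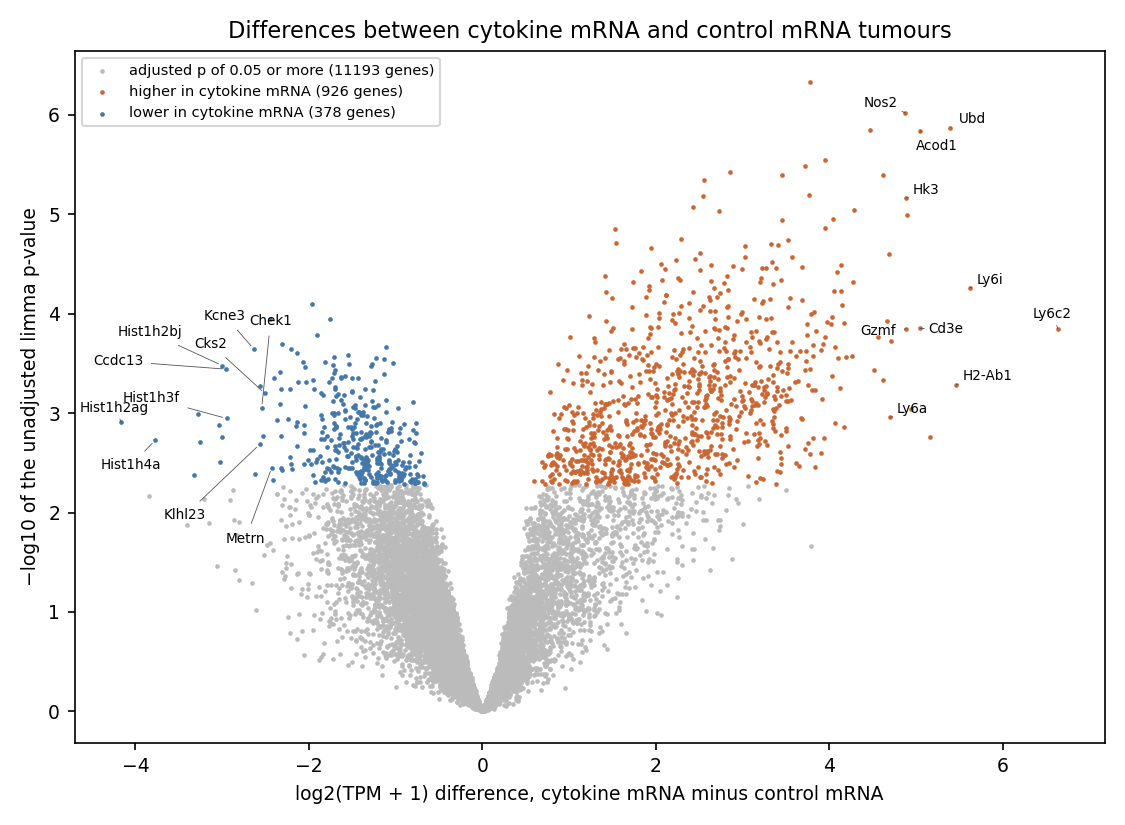
Each point is 1 of the 12497 tested genes; the horizontal axis is the difference in log2(TPM + 1), cytokine mRNA minus control mRNA, and the vertical axis is −log10 of the unadjusted limma p. The 926 genes higher at an adjusted p under 0.05 and the 378 lower ones are coloured, and the 20 genes with the largest rises and falls without overlap between groups are named; Ly6c2 lies farthest to the right, at 6.63.

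The 10 largest rises without overlap between groups were in Ly6c2, Ly6i, H2-Ab1, Ubd, Cd3e, Acod1, Hk3, Gzmf, Nos2 and Ly6a. Ubd, a ubiquitin-like modifier induced by interferon gamma, rose by 5.39 ± 0.59 (SE) on the log2 scale, with a limma adjusted p of 0.00362. Acod1, which makes itaconate in activated macrophages, rose by 5.04 ± 0.56, and Hk3, a hexokinase of myeloid cells, by 4.89 ± 0.63. Gzmf, a granzyme gene, was listed at 0 in all control tumours and reached 67.8 ± 87.8 TPM in the cytokine mRNA tumours (31.5 TPM without library 7). Ly6i, Ly6a and Ly6c2 are close paralogs, and their values could share reads. Without libraries 6 and 7, with 8 tumours, 3 of these 10 genes stayed past the limma threshold; all kept their sign, with log2 changes from 3.28 in Ly6a to 5.19 in Ubd.

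The 10 largest falls without overlap were in Hist1h2ag, Hist1h4a, Hist1h2bj, Ccdc13, Hist1h3f, Kcne3, Klhl23, Chek1, Cks2 and Metrn. The histone gene Hist1h4a fell from 344 ± 83.7 to 67.5 ± 103 TPM, a log2 change of -3.77 ± 0.94 (SE; limma adjusted p = 0.0298); its call was lost in 9 of the fits with 1 library left out, and its cytokine mRNA mean was 22.2 TPM without library 10. Chek1, a DNA damage checkpoint kinase, fell from 39.7 ± 4.10 to 9.02 ± 9.09 TPM (5.40 TPM without library 10), and Cks2, a cyclin-dependent kinase subunit, had a log2 change of -2.51 ± 0.54 (SE). Histone genes have near-identical copies whose reads the counting could split. Whether the use of polyA RNA affected their values was not tested. Without libraries 6 and 7, with 8 tumours, 0 of these 10 genes were past the limma threshold; all kept their sign, with log2 changes from -2.53 in Hist1h2ag to -1.40 in Metrn, and -2.16 in Hist1h4a.

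Interferon-stimulated genes rose together. Of 28 type I interferon-stimulated genes, 25 rose and none fell, and 28 rose adjusted over the list alone. Ifi44 rose from 13.3 ± 3.96 to 186 ± 169 TPM (114 TPM without library 7), the antiviral synthetase Oas3 from 2.14 ± 1.43 to 31.6 ± 14.8 TPM, and the nucleic acid sensor Zbp1 from 52.9 ± 45.8 to 301 ± 70.1 TPM. The mean of the list over the tumours was 4.14 ± 0.68 (SD, n = 5) in control and 6.33 ± 0.46 in cytokine mRNA tumours on the log2 scale (exact permutation, adjusted p = 0.0205). Of 25 interferon-gamma response genes, 21 rose and none fell, and 24 rose adjusted over the list alone. The guanylate-binding protein gene Gbp5 rose from 7.83 ± 6.21 to 117 ± 40.5 TPM, and Cxcl9, a chemokine that attracts activated T cells, from 394 ± 333 to 2857 ± 1022 TPM. The Cxcl9 call was lost in 6 of the fits with 1 library left out. Both lists were called by camera, with an adjusted p = 0.149 with an estimated correlation.

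Genes of the IL-12 and Th1 axis rose in 11 of 14 tested and fell in none, and 13 rose adjusted over the list alone. Ifng, the interferon gamma gene, rose from 1.58 ± 1.45 to 48.2 ± 41.1 TPM (31.7 TPM without library 7), and Tnf rose by 3.95 ± 0.55 (SE) on the log2 scale. The list mean differed by 2.87 on the log2 scale (exact permutation, adjusted p = 0.0205), and camera gave an adjusted p = 0.149 with an estimated correlation. Only 3 of 14 Th2 and Th17 genes could be tested, and none of these passed, over all genes or adjusted over the list alone (camera adjusted p = 0.713). Gata3 was at 11.6 ± 8.84 and 9.52 ± 3.68 TPM in control and cytokine mRNA tumours.

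Antigen presentation genes rose for both MHC classes. Of 20 class I pathway genes, 16 rose and none fell, and 19 rose adjusted over the list alone. H2-Q7, a non-classical class I gene, rose from 4.56 ± 2.65 to 105 ± 87.7 TPM, and the immunoproteasome gene Psmb9 from 53.4 ± 30.2 to 346 ± 133 TPM. H2-Q7 and H2-Q6 are close paralogs. Of 12 class II pathway genes, 10 rose and none fell, and 11 rose adjusted over the list alone. Cd74, the invariant chain of class II molecules, rose from 595 ± 578 to 8792 ± 3829 TPM, and H2-Ab1 from 115 ± 90.4 to 5964 ± 7180 TPM (mean of 2889 TPM without library 7). The list means differed by 2.19 for class I and 2.94 for class II (exact permutation, adjusted p = 0.0205 for each). Both were called by camera, with an adjusted p = 0.149 with an estimated correlation.

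Among 21 chemokine genes tested, 12 rose and none fell, and 18 rose adjusted over the list alone. Ccl5, which attracts T cells and monocytes, rose from 44.3 ± 30.6 to 1172 ± 570 TPM, and the neutrophil chemokine Cxcl2 from 1.62 ± 2.37 to 37.9 ± 22.8 TPM. Among 16 checkpoint and co-stimulatory receptor genes, 13 rose and none fell, and 15 rose adjusted over the list alone; Pdcd1lg2, a ligand of PD-1, rose from 0.215 ± 0.295 to 18.4 ± 11.2 TPM and Havcr2, the gene of TIM-3, from 4.50 ± 2.23 to 42.1 ± 26.6 TPM. Of 14 complement genes, 9 rose and none fell, and 13 rose adjusted over the list alone, with a rise of 3.25 ± 0.81 (SE) on the log2 scale in Cfb. The call of Cfb was lost in 7 of the fits with 1 library left out. The list means of these 3 groups differed with an exact permutation adjusted p of 0.0205 each, and camera gave each an adjusted p = 0.149 with an estimated correlation. Of 14 genes of myeloid suppression and alternative activation, 5 rose and none fell, and 7 rose adjusted over the list alone. Arg1, the arginase of alternatively activated macrophages, rose from 5.29 ± 3.49 to 84.4 ± 70.4 TPM, and Il1rn, the interleukin-1 receptor antagonist, from 19.2 ± 9.49 to 250 ± 151 TPM. That list was called by camera, with an adjusted p = 0.152 with an estimated correlation, and its mean differed by 1.68 (exact permutation, adjusted p = 0.0388). The exact call was lost without any 1 of control libraries 4 and 5 or cytokine libraries 6, 7, 8 and 9 (adjusted p of 0.0518 to 0.0547), with the list median (0.0518) and without libraries 6 and 7 together (0.117).

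**Figure D2:**
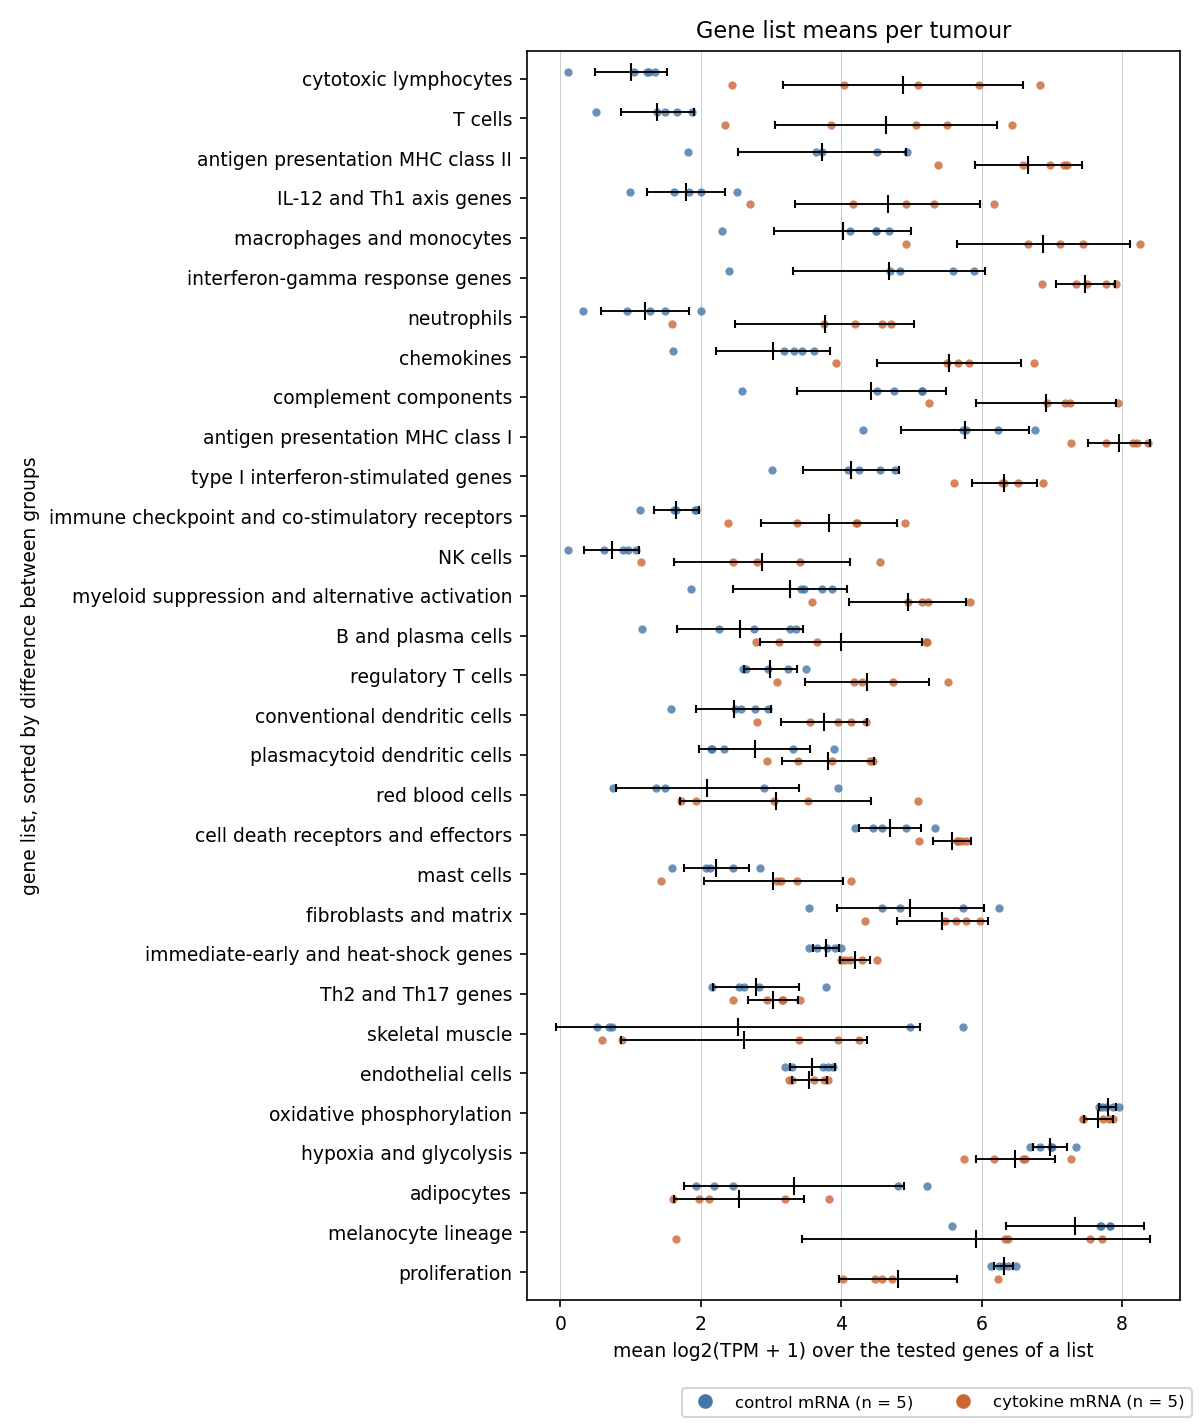
Each point is 1 tumour's mean log2(TPM + 1) over the tested genes of a list (horizontal axis), with lists on the vertical axis sorted by the difference between groups; black marks show the group mean and SD (n = 5 per group). Means of the T cell list were 1.38 ± 0.52 in control and 4.64 ± 1.58 in cytokine mRNA tumours, and those of the proliferation list 6.31 ± 0.13 and 4.81 ± 0.84.

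Markers of T cells and cytotoxic lymphocytes rose. Of 17 T cell genes, 14 rose and none fell, and 17 rose adjusted over the list alone; Trac, the constant segment of the T cell receptor alpha chain, rose from 9.45 ± 8.73 to 483 ± 642 TPM (mean of 210 TPM without library 7), a call lost in 4 of the fits with 1 library left out. Of 15 cytotoxic lymphocyte genes, 14 rose and none fell, and 15 rose adjusted over the list alone; Cd8a rose from 1.16 ± 1.15 to 67.4 ± 76.0 TPM (35.7 TPM without library 7) and Nkg7, a granule protein gene, from 7.21 ± 6.46 to 190 ± 145 TPM. The list means differed by 3.26 and 3.87 on the log2 scale (exact permutation, adjusted p = 0.0205 for each), and camera gave both an adjusted p = 0.149 with an estimated correlation. Of 9 NK cell genes, 5 rose and none fell, and 8 rose adjusted over the list alone; Klre1 rose from 0.164 ± 0.367 to 6.05 ± 3.10 TPM, and Klra8 was listed at 0 in all control tumours. Camera called that list, with an adjusted p = 0.151 with an estimated correlation. Of 6 regulatory T cell genes tested, 2 rose and none fell, and 3 rose adjusted over the list alone. The 2 were Ebi3, a cytokine subunit gene also made by antigen-presenting cells, and Capg, an actin-capping protein gene of myeloid cells, while Foxp3, named after its values were seen, was below the filter. Camera called the list, with an adjusted p = 0.206 with an estimated correlation. Of 4 B and plasma cell genes, none passed, over all genes or adjusted over the list alone (camera adjusted p = 0.0514, and past the threshold in 8 of 21 other settings), and Igkc was at 17.6 ± 20.6 and 85.5 ± 85.7 TPM (limma adjusted p = 0.122).

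Of 19 macrophage and monocyte genes, 15 rose and none fell, and 17 rose adjusted over the list alone. The scavenger receptor gene Msr1 rose from 20.8 ± 9.75 to 266 ± 193 TPM and the lysozyme gene Lyz2 from 80.3 ± 39.9 to 995 ± 828 TPM (656 TPM without library 7). The list mean differed by 2.86 (exact permutation, adjusted p = 0.0205), with an adjusted p = 0.149 with an estimated correlation from camera. Of 8 neutrophil genes tested, from a list of 17, 4 rose and none fell, and 7 rose adjusted over the list alone. Csf3r, the G-CSF receptor gene, was at 5.32 ± 3.72 and 64.8 ± 44.8 TPM. One of the 4 was Acod1, described above as a gene of activated macrophages. The calls of the others, S100a8, Il1r2 and Csf3r, were lost in 9, 7 and 5 of the fits with 1 library left out. For this list camera gave an adjusted p = 0.151 with an estimated correlation. Of 12 conventional dendritic cell genes, 3 rose and none fell, and 8 rose adjusted over the list alone. Xcr1, a receptor of cross-presenting dendritic cells, rose from 0.617 ± 0.622 to 4.69 ± 2.26 TPM, and the list's adjusted p was p = 0.152 with an estimated correlation. Of 6 plasmacytoid dendritic cell genes, 2 rose and none fell, and 3 rose adjusted over the list alone: Runx2, also a bone transcription factor, and Siglech rose among all genes. Camera called that list, with an adjusted p = 0.306 with an estimated correlation, and the exact permutation of its means gave an adjusted p of 0.0861. Its call was also lost with a filter at a TPM of 5 (camera adjusted p = 0.201), by fry (0.0567) and without libraries 6 and 7 (camera adjusted p = 0.0532). None of 4 mast cell genes passed, over all genes or adjusted over the list alone, and of the eosinophil genes only Ear2 was tested, at 0.850 ± 1.17 and 3.17 ± 5.61 TPM.

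The immune lists moved with differences between libraries. Mitochondrial genes took 23.2% ± 4.57 of the TPM in control and 11.3% ± 5.54 in cytokine mRNA tumours (SD, n = 5; exact permutation p = 0.0159, adjusted over 9 library checks p = 0.0476). Library 7 had the highest T cell list mean, 6.43, and listed 276 of 1483 chemosensory receptor genes above 0, against 11 to 22 in control tumours and 20 to 40 in the other cytokine mRNA tumours. The groups differed in that count (exact permutation p = 0.0159, adjusted over 9 library checks p = 0.0476). Ribosomal protein genes scattered by 2.14 (SD, log2) in library 7 and 1.60 in library 6, against 0.37 to 0.54 in control tumours. Library 10 had the lowest T cell list mean of its group, 2.34, and its profile lay with the controls: across genes, which are not independent replicates, its mean r was 0.930 with the control libraries and 0.811 with its own group. Without libraries 6 and 7, camera called 19 lists in place of 20, and the exact permutation of list means called 12 in place of 19.

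**Figure D3:**
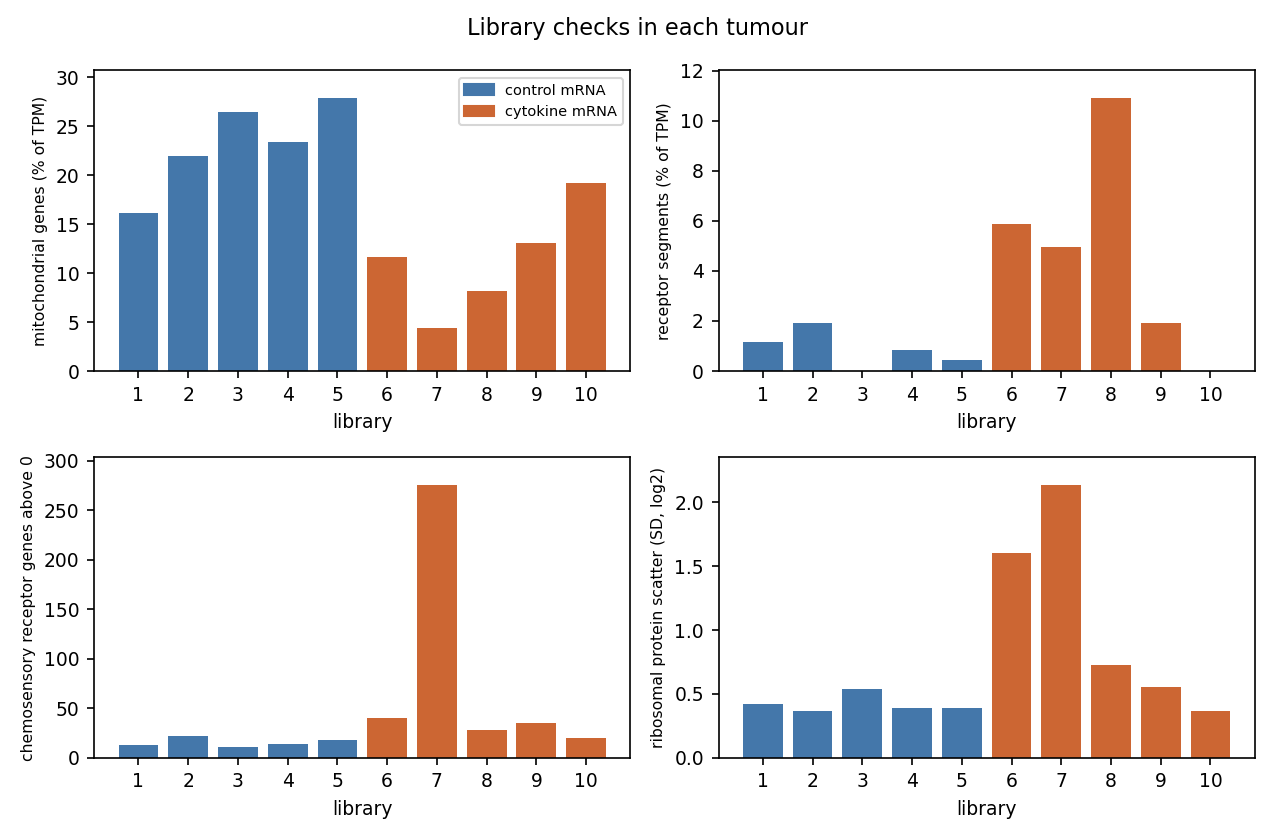
Bars give, for each of the 10 libraries (horizontal axis), the percent of TPM on mitochondrial genes and on receptor segments, how many chemosensory receptor genes were above 0, and the scatter of ribosomal protein genes as an SD on the log2 scale. Library 7 has the most chemosensory receptor genes, 276, and the widest scatter, 2.14.

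Proliferation genes fell. Of 23 genes, 17 fell and none rose, and 22 fell adjusted over the list alone. Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, fell from 165 ± 14.6 to 46.9 ± 44.3 TPM (27.2 TPM without library 10), and the mitotic kinase gene Plk1 had a log2 change of -1.86 ± 0.40 (SE). The list mean differed by -1.51 (exact permutation, adjusted p = 0.0289), and camera gave an adjusted p = 0.182 with an estimated correlation. Library 10, at 6.23, lay within the control range of 6.14 to 6.49, and the other cytokine mRNA libraries lay between 4.02 and 4.72. Without libraries 6 and 7 the list mean differed by -1.13 (exact permutation p = 0.0357), which did not pass adjustment over the lists, and the list median missed the threshold too (exact permutation, adjusted p = 0.0518). Reference and ribosomal protein genes moved with this list. The mean of 74 ribosomal protein genes was 6.56 ± 0.12 (SD, n = 5) in control and 5.86 ± 0.54 in cytokine mRNA tumours on the log2 scale (exact permutation p = 0.0159, adjusted 0.0476). The mean of 14 reference genes was 8.12 ± 0.08 and 7.57 ± 0.48 (exact permutation p = 0.0317, outside the 31 lists), and in library 10, at 8.14, it lay within the control range of 8.01 to 8.21.

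None of 18 melanocyte lineage genes passed, over all genes or adjusted over the list alone, and the list mean was 7.33 ± 0.98 in control and 5.92 ± 2.48 in cytokine mRNA tumours (exact permutation, adjusted p = 0.369). Camera's direction for this list was down (adjusted p = 0.0514), and the list test was past the threshold in 8 of 22 other settings. Tyrp1, a pigment enzyme gene, was at 4659 ± 2380 and 3327 ± 3316 TPM, and Dct, another, at 3316 ± 1562 and 1795 ± 1394 TPM. The list mean was 1.65 in library 7 and 5.58 in control library 1, against 6.33 to 7.84 in the other 8 libraries. Mesenchymal and vascular markers did not pass: 0 of 20 fibroblast and matrix genes, 0 of 16 endothelial genes, 0 of 12 skeletal muscle genes, 0 of 3 adipocyte genes and 0 of 3 red blood cell genes, over all genes or adjusted over the list alone (camera called none of these 5 lists). The fibroblast list had a camera adjusted p of 0.0611, and its test was past the threshold in 6 of 22 other settings. Fn1, fibronectin, was at 1418 ± 1797 and 1490 ± 1238 TPM, and Eng, an endothelial receptor gene, at 156 ± 12.9 and 160 ± 85.3 TPM. The endothelial list had a mean difference of -0.04 and a median of -0.18, while camera's direction against other genes was up, and the mean turned to 0.11 after median-ratio scaling. Skeletal muscle list means ranged from 0.53 to 5.73 among control tumours. Of the skin epithelium genes only Sbsn was tested, and it rose from 9.20 ± 3.76 to 23.1 ± 6.97 TPM.

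Among tumour state and handling lists, 7 of 19 cell death genes rose and none fell, and 7 rose adjusted over the list alone. Casp1, the inflammasome protease, rose from 14.6 ± 14.5 to 111 ± 62.6 TPM, and the pore-forming Gsdmd from 6.71 ± 4.74 to 43.1 ± 25.0 TPM; camera called the list, with an adjusted p = 0.151 with an estimated correlation. Of 14 immediate-early and heat-shock genes, 3 rose and none fell, and 3 rose adjusted over the list alone: Atf3 from 10.4 ± 2.89 to 63.6 ± 27.1 TPM, Dusp1 from 20.5 ± 2.76 to 61.8 ± 27.4 TPM and Jun from 24.2 ± 2.33 to 39.6 ± 6.42 TPM, a call lost in 8 of the fits with 1 library left out. All 3 are stress-response regulators, no heat-shock gene was among them, and camera called the list, with an adjusted p = 0.149 with an estimated correlation; the call was also lost without library 8 (camera adjusted p = 0.0607) and without library 10 (0.0579). Of 18 hypoxia and glycolysis genes, only Pfkfb3, a regulator of glycolysis, rose, over all genes and adjusted over the list alone, from 12.3 ± 3.51 to 68.4 ± 32.4 TPM (camera adjusted p of the list = 0.209). None of 20 oxidative phosphorylation genes passed, over all genes or adjusted over the list alone, with Atp5b at 1729 ± 199 and 1574 ± 439 TPM; the list's mean difference, -0.13, turned to 0.03 after median-ratio scaling.

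**Figure D4:**
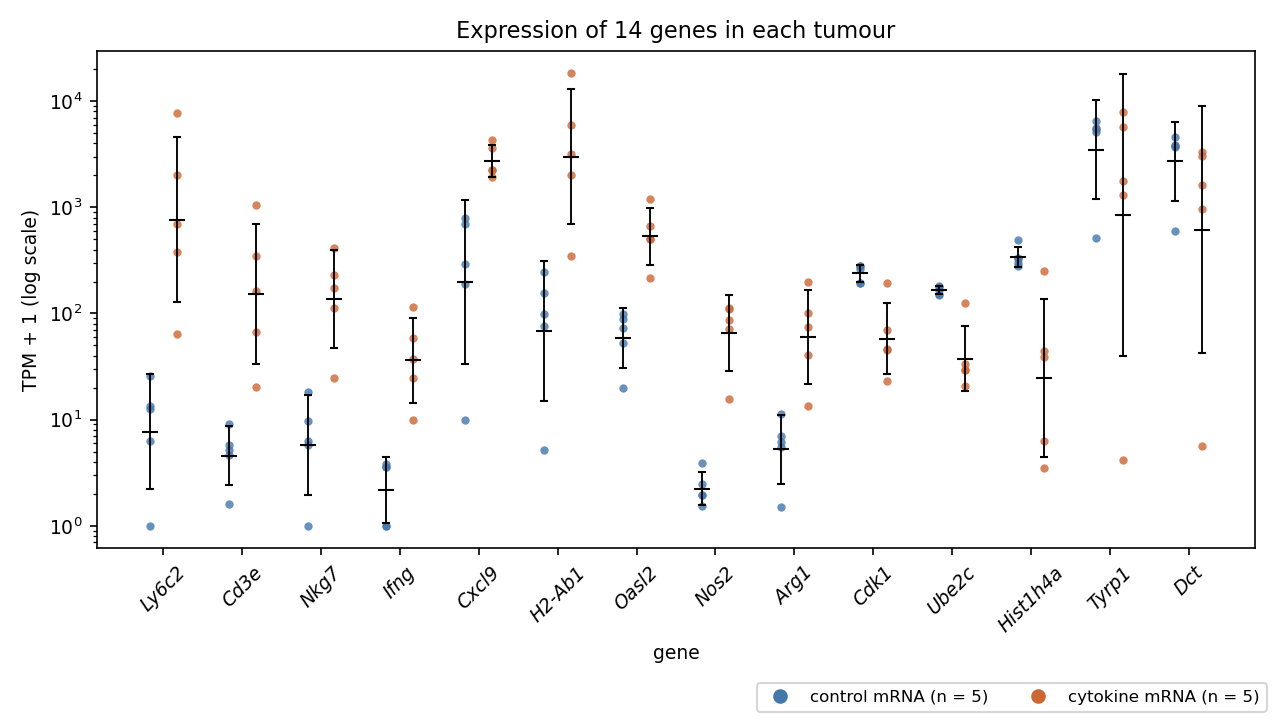
Points are TPM + 1 in each tumour on a log axis (vertical) for 14 genes (horizontal axis), with black marks for the mean and SD of log2(TPM + 1) (n = 5 per group). Ly6c2 averaged 10.8 TPM in control and 2167 TPM in cytokine mRNA tumours, and Cdk1 242 and 74.7 TPM.

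Of the genes that the injected mRNAs encode, Il15ra rose from 16.6 ± 10.1 to 108 ± 71.9 TPM (limma adjusted p = 0.0212), while Il15 was at 8.44 ± 6.57 and 20.5 ± 18.0 TPM and did not pass (adjusted p = 0.266). Il12a, Il12b and Csf2 were below the filter: Il12b averaged 0.318 TPM in control and 1.44 TPM in cytokine mRNA tumours, and Csf2 0.165 and 2.13 TPM. Of 14 interferon alpha genes, Ifna2 and Ifna4 were above 0 in library 7 alone, at 3.08 and 1.16 TPM, and the others were listed at 0 in all 10. The table has 1 value per symbol, which does not separate injected from host transcripts. Of the sex-linked genes Ddx3y was above 0 in library 7 alone, and Kdm5d, Eif2s3y and Uty were listed at 0 in all. None of 14 reference genes passed the limma threshold, although their mean was lower, with a difference of -0.55. Ppia was at 304 ± 31.4 and 126 ± 68.9 TPM without overlap (adjusted p = 0.0797), Tbp was at 85.0 ± 19.0 and 83.0 ± 14.2 TPM, and Gapdh was at 3028 ± 840 and 1607 ± 1284 TPM (adjusted p = 0.174), and the small differences of Tbp, Hprt and Polr2a changed sign between scalings.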

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

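The split count, the comparison of genes with no similar pseudogene, the share of control-silent genes and the ribosomal protein comparison were set before their results were seen; the other tests in this part were chosen after the result was seen. Outliers were sought by the gap to the nearest tumour over the range of a group of 5, above a limit of 0.71. Of 114 group values 13 passed it, and chance alone passes about 1 in 20.

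In control library 5 the gap ratio was 0.786 for the chemokine list, 0.748 for complement, 0.778 for myeloid suppression, 0.757 for cytotoxic lymphocytes and 0.764 for macrophages, each the lowest of its group. Control library 1 was lowest in the melanocyte list, with a ratio of 0.936 and a mean of 5.58 against 7.69 to 7.84 in the other control libraries, and highest in Hist1h2ag, with a ratio of 0.831. Ubd was above 0 in control library 3 and listed at 0 in the other control libraries, which gives a ratio of 1. In the cytokine group, library 10 was lowest in the cell death list (ratio 0.801), Acod1 (0.822) and Nos2 (0.768). Library 7 was lowest in the melanocyte list (ratio 0.772) and highest in chemosensory receptor genes (ratio 0.922).

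Gene groups of which most members were not tested stood above the control level in several cytokine mRNA libraries; 9 of the 477 receptor segments were among the tested genes. Library 7 had 276 chemosensory receptor genes above 0, against at most 22 in control libraries. Receptor segments took 5.87%, 4.95%, 10.9% and 1.93% of the TPM in libraries 6, 7, 8 and 9, against at most 1.92% in control libraries, and library 10 had 0.0117%. The groups did not differ in this share by exact permutation at the threshold (p = 0.0714, adjusted 0.102).

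The rise of immune genes was weighed first. A chance split of the tumours is argued against for the count of changed genes. Of 100 drawn splits of the 10 tumours, only the real one gave 1304 genes, and the highest other split gave 10. The real split was always among the 100, out of 126 possible, so 1 of 100 is the smallest share this could give. A lower melanoma share alone would raise markers found only in other cell types alike. The mean of the T cell and macrophage lists rose by 2.85 more than that of the endothelial and fibroblast lists (log2; exact permutation p = 0.00794, the smallest it can give). These lists were chosen after their differences were seen: 3.26 for T cells, 2.86 for macrophages, 0.45 for fibroblasts and -0.04 for endothelial cells. The p-value therefore cannot decide the question. The lists did not rise alike, but whether melanoma cells also express the endothelial and fibroblast genes was not tested. Libraries 6 and 7 alone do not carry all of the rise of immune genes. Without them, 12 of the 31 lists fixed beforehand passed, such as the T cell list (difference 2.37, exact permutation, adjusted p = 0.0461). The neutrophil list (0.0738) and the myeloid suppression list (0.117) did not. The mean over the 17 called immune lists was higher by 1.93 without them (exact permutation p = 0.0179, the smallest possible). Those 17 lists had been chosen for being higher in all 10 tumours, so that mean is weak support. A response of the tumours to the cytokine mRNA stays open as a hypothesis. A lower melanoma share stays open too, as do differences in tumour size or site of sampling, which the labels do not give.

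For the fall of proliferation genes, loss of transcripts with pseudogene copies is argued against: over the 11 of 23 genes with no similar pseudogene, the list mean still differed by -1.49 (exact permutation p = 0.0159). Whether libraries 6 and 7 alone carry the fall could not be decided by the test. Without them the list mean differed by -1.13 (exact permutation p = 0.0357, adjusted over the lists 0.0738). Libraries 8 and 9, at 4.72 and 4.59, still lay below the control range of 6.14 to 6.49, while library 10, at 6.23, lay within it. Fewer melanoma cells per sample, slower division of those cells and a shift of the libraries not specific to cell division cannot be told apart. The mean of 14 reference genes was lower too, with a difference of -0.55, and in library 10, at 8.14, it lay within the control range. The proliferation mean minus the melanocyte mean differed by -0.10 (exact permutation p = 0.833), but it was 0.73 in control library 1 and 2.37 in library 7, whose pigment genes were low. Sox10, a neural crest transcription factor, was at 334 and 298 TPM in libraries 8 and 9 against 320 to 532 TPM in control libraries, while Mki67, a proliferation marker, was at 42.0 and 26.9 TPM against 109 to 134 TPM (both genes were chosen after their values were seen); Sox10 was at 104 and 2.18 TPM in libraries 6 and 7, so the libraries differ and the question stays open.

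Library 7 stood apart in chemosensory receptor genes, and libraries 6 and 7 in the scatter of ribosomal protein genes. Deeper sequencing of library 7 would add detected genes and not TPM, provided that no filter had set low values to 0. The chemosensory receptor genes of library 7 summed to 237 TPM, against at most 76.1 in any other library. This argues against depth only under that condition, and whether a filter was used is not known. The sum was also higher in each other cytokine mRNA library (33.4 to 76.1 TPM) than in any control library (20.5 to 23.3 TPM). It thus differed between the groups and not in library 7 alone, and whether background differed with the treatment was not tested. Background reads, such as genomic DNA left after the DNase step, are a candidate explanation: of 4943 other genes at 0 in all control libraries, 25.0% were above 0 in library 7 and at most 7.47% in another cytokine mRNA library; a low amount of intact RNA could give the same picture and was not tested. For reads shared with pseudogenes, the number of copies and the size of the deviation had a Spearman rho of -0.0710 across 74 ribosomal protein genes in library 7 (permutation p = 0.550; genes are not independent replicates). A rho at or below 0 or a p of 0.05 or more had been set beforehand to count against it, but that bound was wrong, because a p that misses the threshold excludes nothing and this rho lies within its spread of 0, so this stays open.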

How the results depend on the processing

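All 1304 changed genes that a setting could test kept their direction in every setting. No result changed sign where it was past its threshold in either setting; results that did not pass could change sign, such as the list mean differences of endothelial cells (-0.17 to 0.11), oxidative phosphorylation (-0.27 to 0.04) and skeletal muscle (-0.63 to 0.88). Of the 91 changed genes that the naming rule takes, 44 lost the call with at least 1 library left out and 47 kept it in each such fit. Leaving out libraries 6 and 7 and rescaling without mitochondrial and receptor segment genes were chosen after seeing the data. With each library left out in turn, changed genes ranged from 367 to 3238, higher genes from 321 to 1644, lower genes from 46 to 1594, lists called by camera from 19 to 22 and lists called by exact permutation from 16 to 21; the lowest gene counts came without library 6 and the highest without library 10. Without libraries 6 and 7, 20 genes changed, 19 higher and 1 lower (Gm14322, a predicted gene, chosen after its values were seen), and 12 lists passed the exact permutation test, with 8 tumours in place of 10. Library quality weights gave 2769 changed genes, 1593 higher and 1176 lower. Without a filter on low values 846 changed and 170 were lower, with 17505 genes tested. Lower genes numbered 569 without the 50 most abundant genes, 613 after quantile normalization and 667 without mitochondrial and receptor segment genes. At an adjusted p under 0.01, 61 genes changed, 61 higher and 0 lower. The exact rank test called 0 changed, 0 higher and 0 lower genes (2914 at an unadjusted p under 0.05, against 3813 for limma), because its smallest p, 0.00794, is too large to pass adjustment over 12497 genes at this share of separated genes. With the correlation estimated per list, camera called 0 lists (lowest adjusted p = 0.149), while fry called 19. Apart from the settings whose construction shows it, the cause was not tested. The depth of the libraries is unknown, so what it limits cannot be said.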

Other observations

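All tests in this part were chosen after the results were seen. Gene families were formed by the stem of the symbol, with at least 8 tested genes each, and their direction was the same under the 4 other scalings for each family named here. Of 197 families 23 were called by camera with the preset correlation, 12 higher and 11 lower, and 0 with an estimated correlation (adjusted p = 0.889). Exact permutation of the family means gave no adjusted p under 0.0823. Guanylate-binding protein (Gbp) genes were higher in 11 of 11, and the Ifi genes, induced by interferon, in 12 of 14. Genes with Clec symbols, mostly C-type lectins, were higher in 9 of 17, the Gimap genes of lymphocytes in 4 of 8, Toll-like receptor genes in 4 of 12, and Parp genes in 7 of 12.

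Histone genes were lower in 20 of 52 and higher in 1, Hist1h2ak (named after its values were seen), at 37.2 TPM in control and 265 TPM in cytokine mRNA tumours (limma adjusted p = 0.0402). The family mean differed by -1.55 (exact permutation p = 0.0159). An effect of the polyA RNA preparation or of shared reads on this family was not tested. Mcm genes, several of which license DNA replication, were lower in 5 of 10, and kinesin (Kif) genes in 8 of 32. The falls were not confined to families of cell division: camera also called Rpl (0 of 44 genes lower by limma), Mrpl (2 of 49), Mrps (0 of 29), Polr (0 of 28), Lsm (2 of 13), Rad (5 of 18), Pcdhb (0 of 14) and Rps symbols (5 of 41, kinases included), with mean differences from -0.75 to -0.43.

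The genes past the threshold without libraries 6 and 7 included Cd274, the gene of PD-L1, at 19.3 TPM in control and 193 TPM in libraries 8, 9 and 10, Gzmb at 1.55 and 27.8 TPM, and Il18bp, a secreted inhibitor of IL-18, at 17.2 and 207 TPM. These were chosen after their values were seen.

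One hypothesis was a shift toward cytotoxic genes within the lymphocytes. The cytotoxic list mean minus the T cell list mean was -0.38 ± 0.11 in control and 0.24 ± 0.19 in cytokine mRNA tumours (SD, n = 5), a difference of 0.61 (exact permutation p = 0.00794, adjusted over 4 such comparisons 0.0159). This is in line with such a shift, but both lists lie near the floor in control tumours, where the pseudocount compresses differences. A relatively smaller share of regulatory T cells could not be decided. The regulatory list mean minus the T cell list mean differed by -1.88 (exact permutation p = 0.00794, adjusted 0.0159), yet Foxp3 was below the filter and the tested members include genes of other cells. A shift toward neutrophil over macrophage genes could not be decided, with a difference of -0.30 (exact permutation p = 0.381), and a response weighted toward interferon gamma over type I interferon could not be decided either, with a difference of 0.61 (exact permutation p = 0.135).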
